A study of Homo sapiens with 6 samples.

How the data were processed

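RNA of gefitinib-sensitive HCC827 cells (3 samples) and of the resistant clone (3 samples) was labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. Agilent Feature Extraction 10.7.1.1 is named in the submitters' processing notes. The authors deposited 1 table of log2 intensities with 111087 probe IDs and 6 arrays. No log base is given in the sources used here. The values span 1.16 to 19.19, which as log2 lies within a scanner's range and as natural log would exceed it, so log2 was assumed and every fold change rests on that. The sorted values of the 6 deposited columns differed by at most 0.0047, so the deposited log2 values had already been quantile normalized between arrays. Background correction, the averaging of repeated spots, filters on dim probes and detection flags are not given in the sources used here. Quantile normalization gives every array the same distribution, so a shift of most transcripts in one direction would not be visible.

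The deposited values were used as they stood. The 68 control probes were left out of the main test, which left 111019 probes. Each probe ID occurred once. None of the catalogue or custom IDs matched an ID, symbol or accession in the reference gene table used here (GRCh38.p14), so the planned analysis by gene, the tests of gene lists fixed beforehand and the naming of long noncoding RNAs were not run. For the same reason genomic positions are not given.

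Resistant and sensitive arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior, no covariate, two-sided, Benjamini-Hochberg adjustment). A probe passed at an adjusted p under 0.05 and at least 2-fold. Control probes were tested in a fit of all 111087 rows, with the adjustment over those rows and no minimum fold. The rule for naming probes was set before the data were examined, as were the test and the alternatives not described as added. With no table of names, it allowed the 2 IDs that rose and the 2 that fell by the most, among changed probes whose groups did not overlap and whose higher group lay above the median of all probes. The human PGK1 and GAPDH control probes fall outside that rule. They were chosen after their values were seen, because their IDs name genes.

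The background level of an array was the higher of its dark corner and its structural negative control. A probe at or below it on all 3 arrays of a group has only a bound there. The bound sets the mean of the bright group against the mean, over the arrays of the dim group, of the higher of background and the probe's own signal. It is also given for named probes with some of the 3 arrays at background. Counts of 4-fold and 16-fold differences in the results use the same floor. Spike-in probes are the 10 positive controls of Agilent's viral spike-in series. The limma step was tested on simulated data with the means and spreads of the 111019 probes and 200 changed probes in the upper brightness range. Of 100 probes changed by 1.5 log2 units 64 were recovered with the right sign, and of 100 changed by 3 units 92 were, with 5 false calls. The simulated noise was normal and independent between arrays, and no change was placed below the median level. Recovery of dim probes, and false calls from probes that switch between background and low signal, were therefore not measured.

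The labels number the arrays 1 to 3 in both groups. Whether equal numbers pair the arrays was checked from the correlation of their deviations from the group means, and the numbers were not treated as pairs. Alternatives were another centring, filters on dim probes, another variance model, array weights, the replicate number as a block, other fold minimums and each array left out in turn. Scaling to the spike-in probes and leaving out probes at background on all arrays were added after seeing the data. Single contrasts of control probes used exact permutation tests. Figures were drawn with matplotlib 3.10.9.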

Results

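Transcript levels were measured on 6 one-colour microarrays of HCC827, an established EGFR-mutant human lung adenocarcinoma cell line, and of a gefitinib-resistant clone derived from it. Gefitinib is a kinase inhibitor of the epidermal growth factor receptor. Sensitive parental cells were hybridised on 3 arrays and the resistant clone HCC827-8-1 on the other 3. The titles of the resistant samples end in 8-1, 8-2 and 8-3 while their cell line field names HCC827-8-1 for each, so they were treated as samples of 1 clone. If they were different clones, the spread of the resistant group would be that between clones. Per the labels' protocols, the clone was obtained by raising gefitinib stepwise from 8 to 100 nM over 6 months. The labels do not say whether the 3 arrays of a group came from separate cultures or whether the drug was present at harvest, so the p-values measure only the spread between these arrays, which may be technical.

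The deposited table held 1 log2 intensity for each of 111087 probe IDs per array. Of these, 32776 had catalogue-style Agilent IDs, 78243 had custom-design IDs and 68 were control probes. The sources used here do not pair the catalogue and custom IDs with transcripts. Genes are therefore named only for control probes whose own ID names a human gene. The median level was 4.52 on each array. The brighter of a pair of negative control features on each array, taken as the background level, lay between 1.49 and 1.97, and 72.8% to 80.0% of the tested probes exceeded it. The number of arrays, 3 per group, limits the precision of every value below.

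The comparison of resistant with sensitive cells asked which long noncoding and other transcripts differ with acquired resistance to an EGFR kinase inhibitor. Between the 2 groups, 1144 probes were higher and 1262 were lower in the resistant arrays, 2406 of 111019 in all or 2.17%. The changed probes went about equally in both directions, with 47.5% of them higher. Quantile normalization gives every array the same distribution, which favours such a balance. Without the fold minimum, 3138 probes were higher and 4340 lower. The median fitted change of the 2406 changed probes was 2.63-fold upward and 2.62-fold downward. With signal below background set to the background level of its array, 2281 of them differed by at least 2-fold. On that scale 176 higher and 231 lower probes differed by at least 4-fold, and 15 higher and 14 lower probes by at least 16-fold. A probe was counted as changed at an adjusted p under 0.05 in limma (Benjamini-Hochberg over all tested probes, two-sided) with at least 2-fold between the group means. On all 2406 changed probes the 3 resistant arrays lay on one side of the 3 sensitive arrays, which a call at this threshold largely implies. Over all tested probes the groups were apart in this way on 30.98%, where chance gives 10%. Without sensitive replicate 3 the count was 1316, without resistant replicate 1 it was 1363, without resistant replicate 2 it was 693 and without resistant replicate 3 it was 1078.

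**Figure D1:**
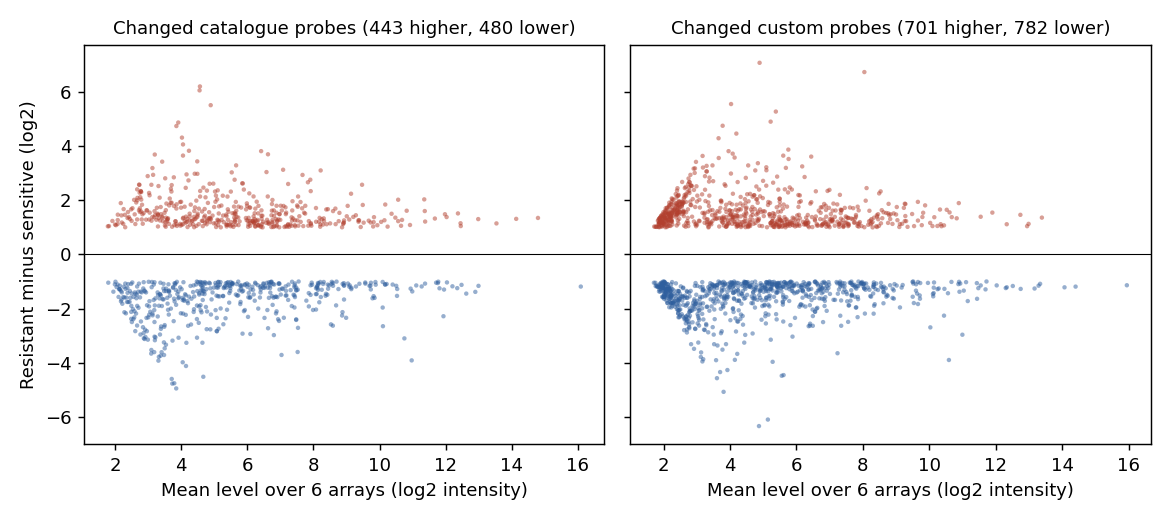
Log2 difference between resistant and sensitive group means (vertical axis) against the mean log2 intensity over 6 arrays (horizontal axis) for the changed probes, with 1 point per probe, catalogue probes on the left and custom probes on the right. Points above 0 (red) were higher in resistant cells and points below 0 (blue) were lower; the 443 higher and 480 lower catalogue probes and the 701 higher and 782 lower custom probes cover both sides at most levels.

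Arrays of one group resembled each other more than arrays of different groups. The Pearson correlation of log2 intensities across probes, which are not independent replicates, was 0.985 to 0.987 within groups and 0.978 to 0.982 between them. The median absolute difference between a pair of arrays was 0.142 to 0.203 log2 units within groups and 0.229 to 0.318 between groups. The median SD per probe was 0.176 in the sensitive arrays and 0.153 in the resistant arrays (n = 3 each). By the median absolute difference the closest pair was resistant replicates 1 and 2, at 0.142. By the correlation it was sensitive replicates 2 and 3, at 0.987.

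The human control probes showed lower PGK1 in the resistant clone. PGK1 encodes phosphoglycerate kinase, an ATP-producing enzyme of glycolysis. Both human PGK1 probes fell to 0.44 times the sensitive level. The level of Human-PGK1_3 was 16.74 ± 0.33 in sensitive and 15.55 ± 0.21 in resistant cells (log2, SD, n = 3), a difference of -1.19 (SE 0.21, limma adjusted p = 0.036). Human-PGK1_5 went from 13.43 ± 0.27 to 12.24 ± 0.22 (log2, SD, n = 3), a difference of -1.18 (SE 0.18, limma adjusted p = 0.028). What the final digit of these IDs stands for is not given in the sources used here. The control probes named for mouse and rat PGK1 that end in 5 had differences of -1.13 (limma adjusted p = 0.024) and -1.12 (limma adjusted p = 0.027) on the same arrays. Mouse-PGK1_3 had a difference of -0.77 that missed the threshold (limma adjusted p = 0.16), and Rat-PGK1_3 was not above background on any sensitive array. Leaving out any one array other than sensitive replicate 1 ended the call of both human PGK1 probes, with limma adjusted p of 0.080 to 0.119 for Human-PGK1_3 and 0.067 to 0.098 for Human-PGK1_5. Without sensitive replicates 2 and 3 in turn Human-PGK1_3 differed by -1.08 and -1.10, and without resistant replicates 1, 2 and 3 in turn by -1.27, -1.22 and -1.07.

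GAPDH, which encodes the glycolytic enzyme acting just before PGK1, had a smaller difference on its human probes that did not pass the test. Human-GAPDH_3 differed by -0.48 (SE 0.14, 95% interval -0.84 to -0.12, limma adjusted p = 0.13) and Human-GAPDH_5 by -0.35 (SE 0.14, 95% interval -0.71 to 0.02, limma adjusted p = 0.24). The probes named for mouse and rat GAPDH went both ways. Mouse-GAPDH_5 differed by 0.26, Rat-GAPDH_3 by 0.13, Rat-GAPDH_5 by -0.25 and Mouse-GAPDH_3 by -0.11 (limma adjusted p of 0.25 to 0.66). Per array, the mean of the PGK1 probes minus that of the GAPDH probes was -1.34 ± 0.19 in sensitive and -2.11 ± 0.05 in resistant cells (log2, SD, n = 3). The exact two-sided permutation p of this difference was 0.1, the smallest that 3 against 3 arrays allow. The 10 spike-in control probes differed between groups by -0.02 on average and by -0.09 to 0.02 individually, and their lowest limma adjusted p was 0.67.

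**Figure D2:**
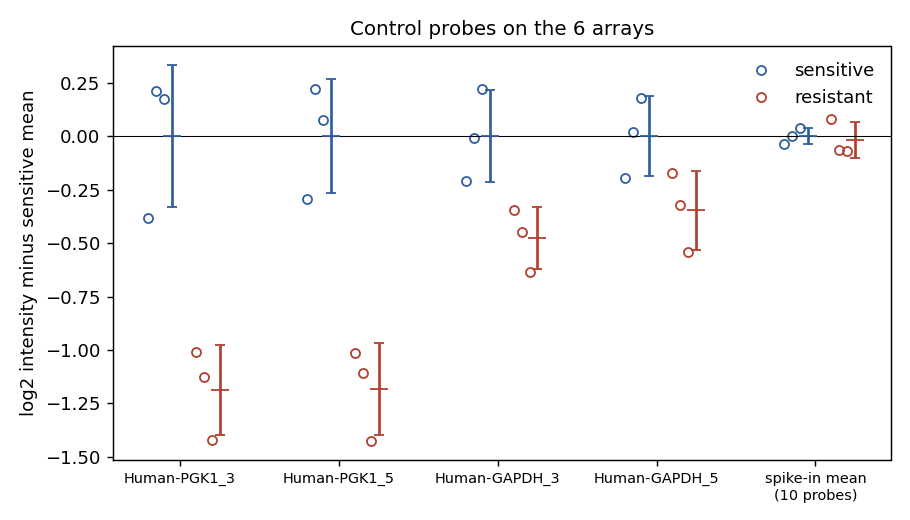
Log2 intensity of the human PGK1 and GAPDH control probes and of the mean of 10 spike-in probes on each array, minus the mean of the sensitive arrays. Open circles are arrays (3 sensitive in blue, 3 resistant in red) and bars are mean ± SD; the PGK1 probes differ by -1.19 and -1.18, and the spike-in mean differs by -0.02.

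Among the unnamed probes, the 2 largest fitted rises were in custom probes. Other probes that rose from background have only bounds, so the order of the largest rises is not known. CUST_89973_PI429545380 was at background on the 3 sensitive arrays and reached 8.44 ± 0.11 (log2, SD, n = 3) in resistant cells. This was at least 102-fold higher, measured from the background level of the sensitive arrays (measured means 1.35 and 8.44, limma adjusted p = 6.02e-05). CUST_34337_PI429545399 rose from 4.67 ± 0.09 to 11.42 ± 0.04 (log2, SD, n = 3), a difference of 6.75 (SE 0.07, limma adjusted p = 6.02e-05). The largest fitted falls were also in custom probes and reached the background, so their sizes are bounds and their order is not known. CUST_1064_PI429545384 was at 8.05 ± 0.10 in sensitive cells and above background on 1 of the 3 resistant arrays (measured means 8.05 and 1.70, log2, n = 3). It was at least 70.6-fold lower in resistant cells, measured from the higher of background and its own signal on each array (limma adjusted p = 0.0019). CUST_6587_PI429545388 was at 8.19 ± 0.10 in sensitive cells and above background on 2 of the 3 resistant arrays (measured means 8.19 and 2.09, log2, n = 3). It was at least 68.3-fold lower by the same measure (limma adjusted p = 0.0046).

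Some changed probes were at background on all 3 arrays of one group. Of the 1144 higher probes, 140 were at background on all 3 sensitive arrays, 124 of them custom and 16 catalogue probes. Of the 1262 lower probes, 128 were at background on all 3 resistant arrays, 100 of them custom and 28 catalogue probes. The fold changes of these 2 sets are bounds. A probe of either set may also be at background on some arrays of the other group. The background level rests on a pair of control features per array. Other splits of the arrays also gave dim probes past the same raw p and fold, as described below.

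Catalogue probes changed more often than custom probes. In the catalogue class 443 probes were higher and 480 lower, 2.82% of the class, and in the custom class 701 were higher and 782 lower, 1.90% of the class. Catalogue probes were brighter, with a median level of 6.068 against 3.796. When the probes were divided by mean level into 10 bins of equal size, numbered from the dimmest, the catalogue share was the higher one in 7 of the 8 bins that held any changed probe. In bin 5 it was 6.22% against 3.32%, and in the brightest bin 1.38% against 0.97%. Bin 3 went the other way, with 0.94% of catalogue and 1.88% of custom probes changed. With the class labels permuted within bins, 724 changed catalogue probes were expected and 923 were found, 1.28 times as many (two-sided permutation p = 2e-04, the smallest that 10000 permutations can give). The permutation treats probes as independent, but neighbouring custom IDs changed together (described below), so this p is too small.

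The share of changed probes depended on the level at which they were measured. It was highest at 4.06% in bin 5 and 1.14% in the brightest bin. In the dimmest 2 bins limma gave 0 changed probes of 22203, where 254 had an unadjusted p under 0.05. Bins are set by the mean over both groups, so a probe that rose or fell by 2-fold can hardly lie in these bins, and the 0 is no sign of stability. The median SE of a difference was 0.06 log2 units in bin 1, 0.44 in bin 4, where it was highest, and 0.10 in the brightest bin. Small changes were thus easier to detect at bright probes than at those of bin 4. The dimmest 3 bins, up to a level of 2.18, held 187 of the changed probes, 165 of them custom. At the same raw p and fold, other splits of the 6 arrays gave up to 146 probes in these bins. Above that level, 2219 probes were changed, 1051 higher and 1168 lower.

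**Figure D3:**
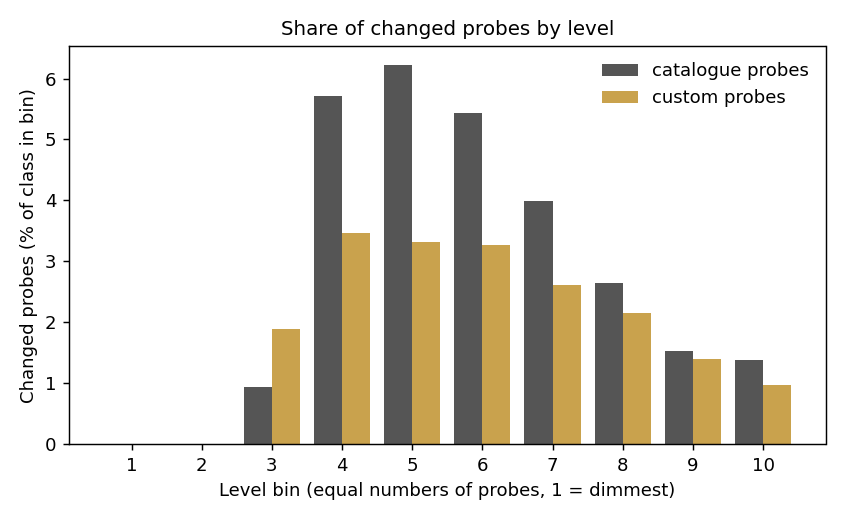
Percentage of catalogue (grey) and custom (ochre) probes counted as changed in each of 10 bins of equal size, ordered by mean log2 intensity over 6 arrays from dimmest (1) to brightest (10). The catalogue share is above the custom share from bin 4 on, and bin 5 shows 6.22% against 3.32%.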

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

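The tests of the PGK1 pattern and of the splits were chosen after the results were seen, and the test of the dim probes was written down before its result was seen.

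Control probes outside the main comparison were searched for any that lay higher on all 3 resistant arrays than on all 3 sensitive arrays and above background. Of 48 control probes above background, 3 did so, where chance gives 2.4. DCP_1_7 was higher by 0.35 log2 units (limma adjusted p = 0.052), DCP_1_4 by 0.14 (limma adjusted p = 0.30) and ERCC-00043_129 by 0.40 (limma adjusted p = 0.25). In the other direction 6 control probes lay lower on all resistant arrays, namely both human and both mouse PGK1 probes, Rat-PGK1_5 and Human-GAPDH_3.

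The lower PGK1 signal of the resistant arrays was -1.18 on average over both human probes. Before normalization, weaker labelling, hybridisation or scaling of the resistant arrays would move PGK1 and GAPDH alike. A loss of signal at very bright probes would lower the GAPDH probes, which are brighter on average, at least as far as PGK1. The change of PGK1 minus that of GAPDH was -0.77 (SE 0.11, exact two-sided permutation p = 0.1, the smallest possible). Quantile normalization included the control probes and had largely removed any loss shared by all probes or set by brightness alone. The contrast therefore cannot decide on either cause, and whether GAPDH itself rose was not tested. Among the 2104 tested probes at least as bright as Human-PGK1_5, the median difference was 0.02, which the normalization largely sets. Of these probes, 0.24% fell at least as far as PGK1. The brighter and the dimmer PGK1 probe fell alike (-1.19 and -1.18). For GAPDH, the brighter minus the dimmer human probe changed by -0.13 (exact two-sided permutation p = 0.1), so there the brighter probe fell further. Culture density, medium, time of harvest and a difference between the clone and its parental line stay open and untested, since each group was 1 kind of cell and the labels give no batch.

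The 187 changed probes of the 3 dimmest level bins (bins of equal size by mean level) were compared with what other splits of the same arrays give at the same raw p (0.0034) and 2-fold minimum. The highest of the 9 other splits, sensitive 1 with resistant 2 and 3 against the rest, gave 146 such dim probes. The next highest gave 110, and the median of the 9 was 87. Among brighter probes the real split gave 2219, the highest other, again that split, 202, and the median was 76. The dim changes are therefore consistent with probes that switch between background and low signal from array to array whatever the group, and a true difference in some of them stays open.

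Over the whole array, the split into resistant and sensitive gave 2406 changed probes, and the highest of the other splits gave 0. It was 1 of 10 splits with a result that large, and 10 splits are too few for a share under 0.05. Every other split mixes resistant and sensitive arrays on both sides. Differences between the groups then add to the residual spread and can lower the counts of those splits. The same limit holds for the counts of dim and brighter probes above. At an unadjusted p under 0.05 the real split had 24716 probes and the highest other split, sensitive 1 with resistant 2 and 3 against the rest, had 7228.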

How the results depend on the processing

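The count of 2406 changed probes was recomputed under 15 alternatives set before the data were examined and 2 added after seeing them. Shifting each array to a common 75th percentile or median left the count at 2406, since the arrays already share their quantiles, so these say nothing about scaling. Scaling to the spike-in probes gave 2400 changed probes, of which 2284 were among the 2406. The count was 7478 with no fold minimum, 3138 of them higher and 4340 lower, and 452 at a fitted 4-fold or more. Leaving out 1 array gave 693 to 1926 changed probes, with the lowest count without resistant replicate 2. Of the probes changed with 1 array left out, 605 to 1473 were among the 2406. The number past 2-fold at an unadjusted p under 0.05 was then 4325 to 5177, against 4352 with all arrays. With the replicate block limma counted 0 changed probes, against 4217 past 2-fold at an unadjusted p under 0.05, and it has 2 residual degrees of freedom in place of 4. Deviations of same-numbered arrays correlated at -0.07, 0.00028 and -0.06, against -0.02 to 0.08 for differently numbered arrays across groups. Equal numbers thus showed no shared deviation, but this cannot show whether they were cultured or processed together. Without probes in the bottom 25% by level 2756 changed, without those below the median 1605 and without those at background on all arrays 2492. The 4 named custom probes passed in 16 of 17 alternatives, all but the block, and Human-PGK1_3 and Human-PGK1_5 passed in 11 of 17. Passing here means an adjusted p under 0.05. The other fold minimums cannot change that p, and the shifts to a common 75th percentile or median barely change it. Passes under these settings repeat the main fit and add no support. Human-GAPDH_3 passed in 1, without the probes below the median (limma adjusted p = 0.042), and Human-GAPDH_5 in 0. No value reversed. Alternatives for genes and gene lists were not run, for want of probe names. Signal near background limits the comparison: 10177 probes were at background on all 6 arrays.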

Other observations

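Custom probes with neighbouring ID numbers changed together. Neighbouring IDs are next to each other in number order among the deposited IDs of a set, with numbers a median of 10 apart. Among the 9 sets of custom IDs, ordered by number, 156 neighbouring pairs were both changed in the same direction and 6 in opposite directions. Runs were picked where a window of 11 IDs held more than 5 changed probes of one direction, and were trimmed to begin and end at one. There were 3, and their high share of changed probes follows from that choice. In one run of 9 neighbouring IDs, 8 rose in the resistant clone. Of these 9 probes 5 were at background on an array of one group, and with the background level as a floor the median difference was at least 4.05 log2 units. In another run of 9, 7 fell, with a median of -2.23, and in a run of 6 all 6 fell, with a median of -1.41.

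This pattern was noticed in the data and its tests were chosen afterwards. A chance order of the IDs was tested by permuting the changed state among IDs of one set and one level bin. The 156 same-direction pairs compare with a median of 15 and a highest value of 28 in 1000 permutations (one-sided permutation p = 0.001, the smallest they can give), and no permuted window of 11 IDs held more than 5 changed probes of one direction, where the data held 8. The correlation of log2 differences across pairs was 0.12 for direct neighbours, 0.04 at 3 steps and 0.01 at 10 steps. A candidate explanation is that neighbouring IDs target one transcript or near-identical transcripts. The levels of the probes cannot decide it. A pair that changed together had a median gap in level of 0.877 log2 units, against 2.24 for random changed pairs. Neighbours always share a set of IDs, while the random pairs were drawn over all sets, whose median levels ran from 2.29 to 5.24. Closer levels of neighbours can therefore be partly built in, and the gap of unchanged neighbours is not given. Levels of different probes depend on probe sequence too. Transcripts of one locus that change together, by regulation or copy number, stay open, since what the ID order follows is not given in the sources used here. Under either reading, 2406 changed probes may count some loci more than once.

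The sets of custom IDs differed in their share of changed probes, from 1.33% to 2.57%, and in their median level, from 2.29 to 5.24.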
